A study of Macaca fascicularis with 38 samples.

How the data were processed

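The libraries were unstranded, single-end, poly-A selected and sequenced on a HiSeq instrument, per the labels. The tools named are STAR 2.5.2b, HTSeq 0.6.1p1 and DESeq2 without a version, per the submitters' processing notes, and their settings are not given in the sources used here. The genome build and annotation are not given in the sources used here. The deposited per-sample values are TPM, and the authors' deposited log2 fold changes and FDR-adjusted p-values for drinkers and for controls come in the same table, per the file headers. The design had allowed for counts. Since the values were TPM, its stated fallback was used, limma-trend on log2(TPM + 1). The table holds 29958 genes in 32 libraries. Groups before and after and the animal numbers come from the sample titles, and the marks of drinkers and controls come from the table header, which the labels do not repeat. The after biopsies of 6 animals were not analysed here. RNA codes in the titles are 140430 for 16 libraries, all of cohort 9, 151215 for 13 and 171120 for 3, and the codes differ between the biopsies of animals X10226, X10227 and X10232.

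Genes with a mean TPM of at least 1 were tested, 15324 in number, with limma 3.58.1 in R 4.3.3 and the animal as a block, at a Benjamini-Hochberg adjusted p below 0.05. The log2 values are after minus before. The comparison of all 16 pairs, the cohorts and their interaction were fixed before the data were examined. The split into drinkers and controls and their difference were added once the table header had been seen. The pairing rests on the animal numbers. The deviations of an animal's 2 libraries from the group means had correlations from 0.07 to 0.54 with a median of 0.33, above 0.1 in 14 of 16 animals. Libraries of different animals were not compared in this way, so these values do not test the pairing. As a check of the TPM and a measure of depth, whole reads were recovered from the steps between TPM values of a library. This succeeded for 29411 of the 29437 genes above 0 in 2 or more libraries (99.9%, within 1e-06 of a whole number). The other 26, mitochondrially encoded genes among them, were too abundant and are missing from the read counts. Between 20749 and 26947 genes were above 0 per library. Median scaling set the median log2 value of each library equal, and limma-voom was run on the recovered reads.

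The 34 gene lists, 463 symbols of which 441 are in the table and 419 were tested, were fixed by name from general knowledge. Each was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. A test added later took, per animal, the median change of the list minus the median over all genes, with an exact sign-flip test over animals, or a permutation test of animals for differences. Members were counted over all genes and adjusted over the list alone. Genes were named by a rule fixed in advance. Among called genes with 1 direction in at least 12 animals (3550 rising, 383 falling), it takes the 12 largest rises and falls at or above the median mean level of 11.41 TPM and the 3 smallest p in each direction. It adds up to 4 members per list (some are not reported here), 5 genes per direction for the cohort interaction and for the authors' control calls, and GFAP, MBP, SLC17A7, GAD1, FOS and HBB. The genes named for the difference between drinkers and controls, the changes called in controls and SIK1, GPR3 and TRIB2 were chosen after their values were seen.

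In simulated data with 200 of 15324 genes changed by a log2 value of 0.5, the 16-pair fit called 72% of them, the drinker fit 42%, the control fit 10%, the difference 0.5%, cohort 9 33.5%, cohort 13 31% and the cohort interaction 3%. With a change of 1 these were 98.5%, 95%, 83%, 72%, 89%, 90% and 66%. In the same order, 7.7%, 7.7%, 9.1%, 0%, 4.3%, 4.6% and 0% of the calls were unchanged genes at 0.5. At 1 these shares were 6.2%, 8.2%, 7.8%, 7.1%, 3.3%, 5.3% and 2.9%, so some lay above the nominal 5%. The sign-flip test gave p = 3.05e-05 for a raised list and p below 0.05 for 5 of 100 unchanged lists. The recovery of reads returned 100% of 2421 simulated genes, 99.13% with the true reads. Alternatives were no animal block, median and trimmed-mean scaling, other filters and pseudocounts, robust empirical Bayes, array weights, pairs with a single RNA code, composition covariates (mean marker level of neurons, oligodendrocytes and astrocytes), the mitochondrial percent as a covariate, TPM without mitochondrial genes, limma-voom, separate fits and leaving out each animal. Figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.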

Results

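Gene expression was measured by RNA sequencing in biopsies of prefrontal cortical area 46 of cynomolgus macaques, sampled once before and once after a period of voluntary ethanol drinking. The labels list 38 samples from 22 animals of 2 cohorts, named 9 and 13, with 16 biopsies taken before and 22 after. The deposited table holds a before and an after biopsy of 16 animals, 8 per cohort, which makes 32 libraries. The after biopsies of the remaining 6 animals were not analysed here. The header of that table marks 10 of the 16 animals as drinkers, 5 in each cohort, and 6 as controls, 3 in each cohort, whereas the labels give every sample an ethanol treatment. The marks of the header were used here, so that before and after name the first and the second biopsy in both kinds of animal. Neither the interval between the biopsies nor the amounts drunk are given in the sources used here. Between 11.8 and 36.7 M reads per library were recovered from the TPM values, with a median of 14.9 M in cohort 9 and 31.8 M in cohort 13. These counts leave out 26 genes too abundant to recover, mitochondrially encoded ones among them, so the libraries held more reads than this. Animals are named here by their column names in the deposited table. The 13 mitochondrially encoded genes took 41.7% ± 9.73 (SD, n = 16) of the TPM before and 36.5% ± 5.2 after, a mean change of -5.2 ± 7.68 percentage points that was negative in 13 of 16 animals. A smaller share of these abundant transcripts raises the TPM of all other genes, and the median change over the 15324 tested genes was a log2 value of 0.17.

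**Figure D1:**
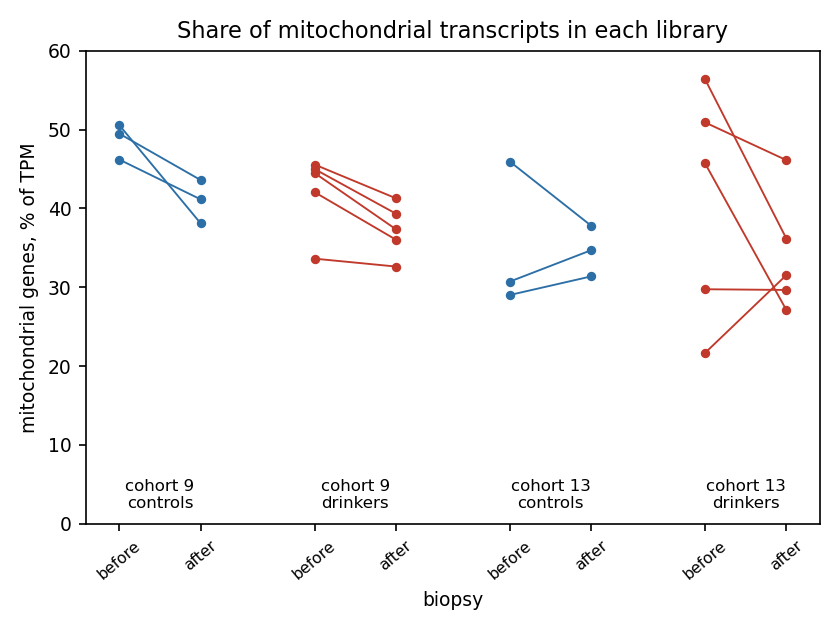
Percent of the TPM of each library that fell on the 13 mitochondrially encoded genes (vertical axis) in the before and the after biopsy (horizontal axis), with a line per animal, for controls (blue) and drinkers (red) of cohorts 9 and 13. The share was lower after in 13 of 16 animals.

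The comparison of the second with the first biopsy asked which genes change in this cortical area over the course of the experiment, in all 16 animals together. DUSP4, a phosphatase that inactivates MAP kinases, rose from 1.80 ± 0.69 TPM (SD, n = 10) to 11.6 ± 3.29 in drinkers and from 1.86 ± 1.05 (n = 6) to 11.9 ± 1.91 in controls. Its log2 change was 2.19 ± 0.11 (SE, n = 16, adjusted p = 1.05e-10) and was positive in 16 of 16 animals. The related phosphatase DUSP6 rose by a log2 value of 1.86 ± 0.18, and the receptor tyrosine kinase signalling inhibitors SPRY4 and SPRY2 rose by 1.56 ± 0.12 and 1.15 ± 0.12, each in 16 of 16 animals. The splicing kinase CLK1 rose by 1.48 ± 0.13, the opsin OPN3 by 1.20 ± 0.15, the prohormone convertase PCSK1 by 1.28 ± 0.23, the Wnt modulator SFRP2 by 1.25 ± 0.28 and the galactosyltransferase B3GALT2 by 1.15 ± 0.23. PCSK1 and SFRP2 were higher in 13 animals, B3GALT2 in 14, and CLK1 and OPN3 in 16. Among the genes that fell, BBC3, which encodes a mediator of apoptosis, the small GTPase gene RRAD and the scavenger receptor gene SCARF2 changed by -0.72 ± 0.09, -0.68 ± 0.09 and -0.71 ± 0.10 and were lower in 16 of 16 animals. So was the glycosyltransferase gene LFNG at -0.63 ± 0.09. The metabolic and transport genes SDS, APOC1, SLC38A5 and OSGIN1 fell by 0.71, 0.86, 0.57 and 0.54. By limma-trend with the animal as a block, 5608 of 15324 genes changed at an adjusted p below 0.05, 5042 higher and 566 lower. Scaled to a common median per library, 3834 genes changed, 1537 higher and 2297 lower. The share of higher calls was 89.9% as deposited and 40.1% after scaling. With the marker levels of neurons, oligodendrocytes and astrocytes as covariates 108 genes changed, 59 of them also called in the same direction without covariates, among them DUSP4, DUSP6, SPRY4, SPRY2, CLK1, BBC3 and RRAD. Of the named genes compared in that fit 58 lost their call, PCSK1, SFRP2, OPN3, B3GALT2, SCARF2 and LFNG among them. Another 15 turned sign, which counts any crossing of 0. A lost call came with a smaller estimate for HSPA8, 0.66 without and 0.15 with the covariates (adjusted p = 0.412 by limma-trend). It came with a larger one for FOS, 1.15 and 1.45 (adjusted p = 0.297). The lower count thus does not by itself show that composition accounts for the changes.

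**Figure D2:**
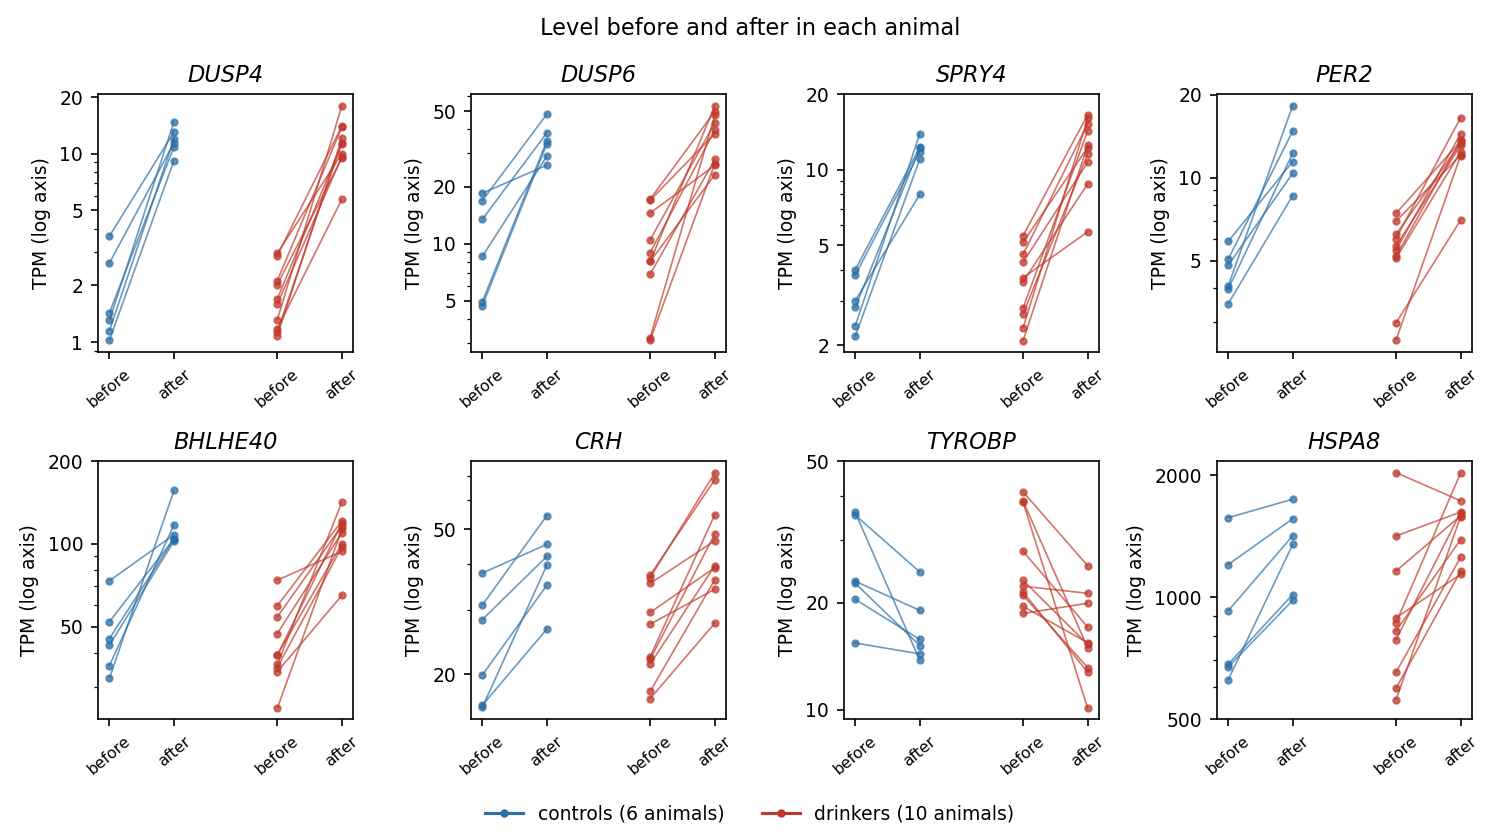
TPM on a log axis before and after in each animal, joined by a line, for 6 controls (blue) and 10 drinkers (red), for DUSP4, DUSP6, SPRY4, PER2, BHLHE40, CRH, TYROBP and HSPA8. DUSP4 lay between 1.02 and 3.65 TPM in the before biopsies of controls and between 9.20 and 14.8 in their after biopsies.

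Genes of the daily clock split. PER2, a repressor of the clock, rose by a log2 value of 1.19 ± 0.09 (SE, n = 16, adjusted p = 8.56e-08) and the clock-controlled repressor BHLHE40 by 1.30 ± 0.12, both in 16 of 16 animals. CRY1 rose by 0.51 ± 0.12, whereas the clock repressor CIART fell by 0.53 on the same scale. CRY1 lost its call with the composition covariates at 0.13 (adjusted p = 0.702) and CIART kept it at -0.80 (adjusted p = 0.0379). Of the 16 clock genes tested 6 were higher and 1 lower, 7 and 1 adjusted over the list alone, and 5 were higher and 5 lower after median scaling. As deposited, genes that respond early to neuronal activity were higher more often than not: EGR1 rose by 1.10 ± 0.18, NR4A1 by 1.003 ± 0.18, NR4A3 by 0.99 ± 0.13 and EGR4 by 0.78 ± 0.14. FOS, fixed in advance, rose by 1.15 ± 0.37 as deposited (adjusted p = 0.0217) in 11 of 16 animals, but did not pass after median scaling (adjusted p = 0.0673). It had -0.06 in cohort 9 and 2.37 in cohort 13, a difference that did not pass (adjusted p = 0.169). Of 17 immediate early genes 11 rose as deposited, 11 adjusted over the list alone and 6 after median scaling, and none fell in any of these. The list stood above other genes by camera (adjusted p = 0.0120), not with an estimated correlation (adjusted p = 0.903 with an estimated correlation) and not without drinker X10230 (adjusted p = 0.0943). Its median per animal lay above that of all genes in 13 of 16 animals by 0.50 ± 0.72 (SD, exact sign-flip test, adjusted p = 0.0606). The mean was 0.044 in cohort 9 and 0.945 in cohort 13, and the difference did not pass (permutation test, adjusted p = 0.145). The clock list did not pass camera (adjusted p = 0.676).

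Microglial and leukocyte transcripts were lower in the after biopsies. The microglial adaptor TYROBP fell by a log2 value of 0.61 (SE 0.12, n = 16, adjusted p = 0.00168) in 15 of 16 animals, and LAPTM5, ITGAM and the complement gene C1QC fell by 0.54, 0.65 and 0.40. Of 14 microglial markers 10 were lower and 0 higher, 10 were lower and 1 was higher adjusted over the list alone, and 12 were lower after median scaling. The neutrophil and monocyte genes S100A8, S100A9 and FCN1 fell by 2.05, 2.26 and 1.01, PTPRC of leukocytes and microglia fell by 0.71, and MNDA of myeloid cells fell by 0.96. In drinkers before, S100A8 and S100A9 varied widely, at 50.9 ± 121.9 and 108.2 ± 240.3 TPM (SD, n = 10). S100A8, S100A9, FCN1 and PTPRC had log2 changes of -3.69, -4.20, -1.86 and -1.22 in cohort 9, each called, and of -0.41, -0.32, -0.16 and -0.21 in cohort 13, none called, and the differences between cohorts did not pass (smallest adjusted p = 0.166). The first 4 were the calls among 8 blood cell markers tested, 4 adjusted over the list alone and 5 after median scaling, without MNDA, which is in no list. The haemoglobin gene HBB had a log2 change of -0.29 ± 0.76 (adjusted p = 0.78), with 8 of 16 animals higher and 8 lower. It changed by -1.834 in cohort 9 and 1.253 in cohort 13, neither called, and the difference did not pass (adjusted p = 0.65). In drinkers HBB changed by -1.302 and in controls by 1.395, neither called, and this difference did not pass (adjusted p = 0.634). Among innate immune genes the cytokine genes CCL2, TNF and CCL3 fell by 1.39, 0.99 and 1.34, and NFKBIA fell by 0.30, in a list of 15 with 6 lower and 1 higher, the same numbers adjusted over the list alone, and 9 lower after median scaling. The genes ARPC1B, CFD and IFI27 fell by 0.65, 0.58 and 0.53. Taken per animal, the median change of the microglial list lay below that of all genes by -0.47 ± 0.33 (SD, n = 16) in 14 animals, that of the innate immune list by -0.43 ± 0.51 in 14 and that of the blood list by -1.03 ± 1.48 in 11 (exact sign-flip tests, adjusted p = 0.00208, 0.0045 and 0.0388). In cohort 9 and cohort 13 these were -0.61 and -0.32 for the microglial, -0.72 and -0.14 for the innate immune and -1.78 and -0.28 for the blood list, and the differences did not pass (permutation tests, adjusted p = 0.392, 0.145 and 0.299). All 3 lists passed camera (adjusted p = 7.71e-12, 5.03e-07 and 5.03e-07), and none did so when the correlation was estimated (adjusted p = 0.372, 0.458 and 0.458 with an estimated correlation). The innate immune list also lost its camera call with the composition covariates (adjusted p = 0.68). With the composition covariates the log2 change of TYROBP was -0.23 (adjusted p = 0.577). Those of S100A8 and S100A9 were -0.75 and -0.71 in that fit (adjusted p = 0.711 and 0.765).

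Heat shock and stress peptide genes were higher after. The chaperones HSPA8, DNAJB1, HSPH1 and DNAJA1 rose by 0.66 ± 0.11, 0.61 ± 0.09, 0.81 ± 0.14 and 0.71 ± 0.13 on the log2 scale (SE, n = 16). Of 11 heat shock proteins 10 rose as deposited, 10 adjusted over the list alone and 6 after median scaling. The list median per animal lay above that of all genes in 16 of 16 animals, by 0.32 ± 0.14 (SD, exact sign-flip test, adjusted p = 0.00104), and passed camera (adjusted p = 3.74e-04, and adjusted p = 0.458 with an estimated correlation). CRH, the corticotropin-releasing hormone, rose by 0.75 ± 0.09 in 16 of 16 animals and kept its call with the composition covariates at 0.59. The glucocorticoid receptor gene NR3C1 rose by 0.76 ± 0.13, the neuropeptide gene ADCYAP1 by 0.73 ± 0.14 and CRHBP by 0.50 ± 0.11. Of the 13 glucocorticoid response and stress peptide genes 7 rose, 7 adjusted over the list alone and 6 after median scaling. That list lay above all genes in 13 of 16 animals by 0.19 ± 0.24 (SD, exact sign-flip test, adjusted p = 0.0349), and did not pass camera (adjusted p = 0.0918). The log2 change of HSPA8 was 0.15 with the composition covariates (adjusted p = 0.412).

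**Figure D3:**
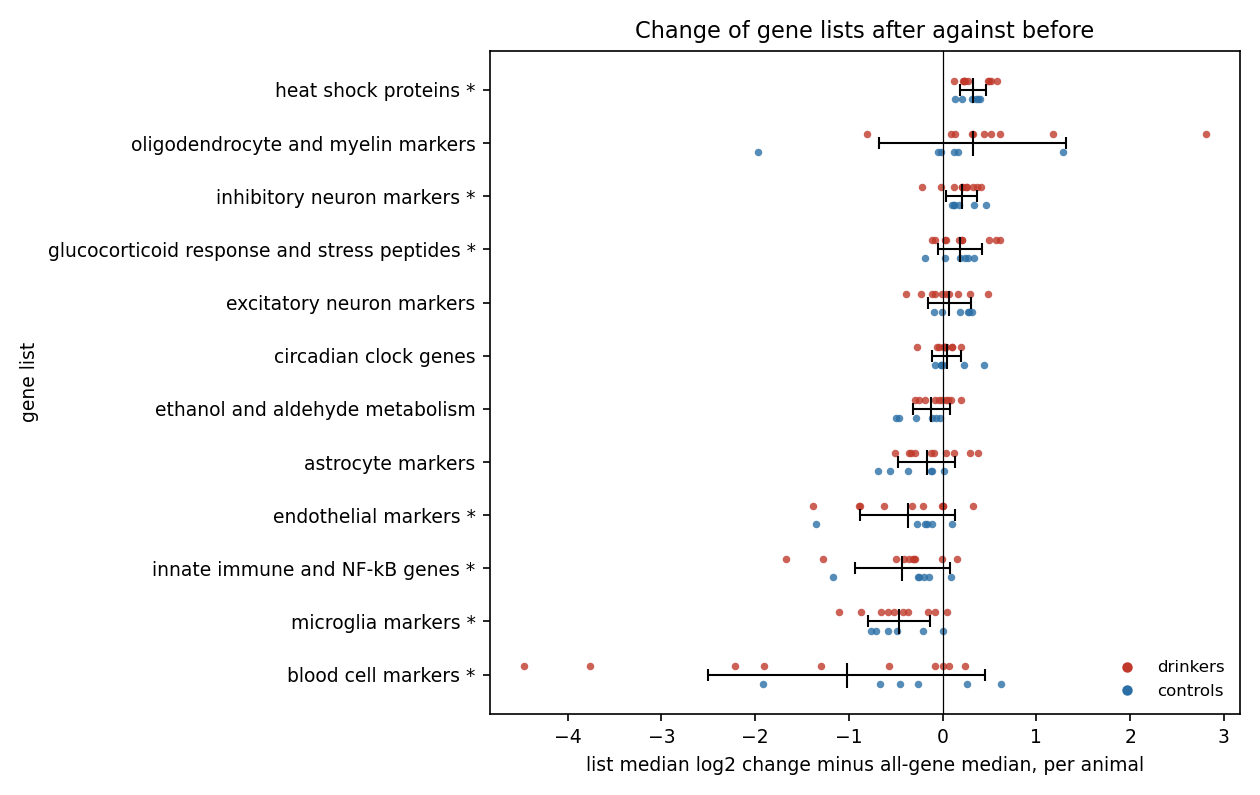
Median log2 change of the genes of a list minus the median over all genes (horizontal axis), 1 point per animal, for drinkers (red, 10) and controls (blue, 6), with the mean and SD over the 16 animals in black. The 12 lists shown are the 7 that passed the exact sign-flip test over animals (star) and 5 others. Heat shock proteins lay above 0 in 16 animals and microglial markers below 0 in 14.

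Single markers of excitatory and inhibitory neurons rose as deposited, and the difference between these 2 lists was not tested. NEUROD6, a transcription factor of excitatory neurons, rose by a log2 value of 1.17 ± 0.16 (SE, n = 16) in 16 of 16 animals and stayed called after median scaling at 0.94. FEZF2 and RORB rose by 0.59 and 0.89. Of 10 excitatory markers 5 were higher, 5 adjusted over the list alone. After median scaling 4 were higher and 2 lower. SLC17A7, the vesicular glutamate transporter, had a change of 0.05 ± 0.09 (adjusted p = 0.664). The inhibitory neuron genes CCK, LHX6, GAD2, RELN and GAD1 rose by 0.34, 0.47, 0.56, 0.62 and 0.37 as deposited, of which CCK and GAD1 did not pass after median scaling (adjusted p = 0.411 and 0.0985). Of 13 inhibitory markers 10 rose, 11 adjusted over the list alone and 3 after median scaling. The inhibitory list lay above all genes in 14 of 16 animals by 0.20 ± 0.17 (SD, exact sign-flip test, adjusted p = 0.00545), and passed camera (adjusted p = 0.00532, and adjusted p = 0.458 with an estimated correlation). The excitatory list did not pass either test (camera adjusted p = 0.787).

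Single receptor, channel and synaptic genes rose as deposited, and their lists did not pass camera. The mean marker level of neurons was higher by 0.37 ± 0.31 (SD) in 13 of 16 animals as deposited and by 0.14 ± 0.14 in 15 after median scaling. With the composition covariates the changes of GRIA2 (-0.06), GRIA3 (-0.14), GRIN2B (-0.11), GRM8 (-0.10), GRM4 (-0.03), GABRA4 (-0.17), DLG3 (-0.13), CACNA2D3 (-0.07) and SCN3A (-0.02) turned sign. A turned sign means only that the estimate crossed 0, and several of these values lie near 0. GABRA4 and GABRB2 of the GABA-A receptor rose by 0.78 and 0.54, in a list of 13 subunits with 5 higher, 5 adjusted over the list alone and 3 median-scaled. The AMPA and kainate receptor subunits GRIA2, GRIA3, GRIA1 and GRIK2 rose by 0.56, 0.41, 0.36 and 0.23, in a list of 9 with 4 higher, 5 adjusted over the list alone, and 1 higher and 1 lower median-scaled. Of 6 NMDA receptor subunits GRIN2B and GRIN2A rose by 0.76 and 0.43 and GRIN2C fell by 0.44, with 2 higher and 1 lower adjusted over the list alone and 0 higher and 1 lower median-scaled. Of 6 metabotropic glutamate receptors GRM8, GRM4, GRM5 and GRM2 rose by 0.53, 0.34, 0.40 and 0.34, with 5 higher adjusted over the list alone and 1 higher and 1 lower median-scaled. The serotonin receptor HTR1E and the dopamine receptors DRD5 and DRD1 rose by 0.57, 0.81 and 0.50. In all 11 of 21 GABA-B, opioid, cannabinoid and monoamine receptor genes rose, 12 adjusted over the list alone, and 4 were higher and 1 lower median-scaled. The potassium channels KCNN2 and KCNA4 rose by 0.59 ± 0.08 and 0.77 ± 0.10 in 16 of 16 animals. Of 19 such channels 11 were higher and 1 lower, 12 and 1 adjusted over the list alone and 7 and 1 median-scaled. Of 15 sodium and calcium channels 5 rose, among them CACNA2D3, SCN3A and SCN8A by 0.44, 0.52 and 0.43, with 4 higher adjusted over the list alone and 2 higher and 1 lower median-scaled. The presynaptic genes VAMP1, SYT2, NSF and SV2B rose by 0.61, 0.91, 0.62 and 0.55, in a list of 23 with 10 higher, 11 adjusted over the list alone, and 6 higher and 2 lower median-scaled. Of 21 postsynaptic scaffold genes DLG3 and DLG1 rose by 0.35 and 0.41 and SHANK3 fell by 0.35, 0 passed adjusted over the list alone, and 0 were higher and 10 lower median-scaled. HAPLN4 and HAPLN1, link proteins of the matrix around neurons, rose by 0.94 and 0.39 among 10 matrix genes, 2 adjusted over the list alone, with 1 higher and 1 lower median-scaled. BDNF, VGF and CREB1 rose by 0.73, 0.74 and 0.49 among 8 neurotrophin signalling genes, 3 adjusted over the list alone, with 3 higher and 1 lower median-scaled. As deposited none of these lists passed camera, with adjusted p from 0.0633 for the monoamine and peptide receptor list to 0.983 for the matrix list. After median scaling camera placed that receptor list (adjusted p = 0.015) and potassium channels (adjusted p = 0.027) above and postsynaptic scaffold genes (adjusted p = 0.0495) below other genes. As deposited each of these 3 had an adjusted p = 0.903 with an estimated correlation, which was not run on the median-scaled values.

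Single genes of the glial and vascular lists were called in both directions. UGT8, an enzyme of myelin lipid synthesis, rose by 1.05 ± 0.26 (SE, n = 16) in 12 of 16 animals, and ERMN and CLDN11 rose by 0.90 and 0.69, while MBP had a change of 0.28 ± 0.24 (adjusted p = 0.368). Of 13 oligodendrocyte markers 4 rose as deposited, 2 adjusted over the list alone and 1 median-scaled (camera adjusted p = 0.411). Of 8 precursor markers none was called as deposited or adjusted over the list alone, with 2 lower median-scaled (camera adjusted p = 0.0855). GFAP, the astrocyte filament gene, rose by 0.39 ± 0.15 as deposited (adjusted p = 0.0431) in 10 of 16 animals and did not pass after median scaling (adjusted p = 0.486). ALDH1L1 fell by 0.23. These were the 2 calls among 12 astrocyte markers, 0 adjusted over the list alone, and 5 were lower median-scaled (camera down, adjusted p = 0.0413, and adjusted p = 0.903 with an estimated correlation). ABCB1, a transporter of the blood-brain barrier, fell by 0.54 and was the single call among 11 endothelial markers, also adjusted over the list alone, with 7 lower median-scaled. The endothelial list lay below all genes in 12 of 16 animals by -0.37 ± 0.51 (SD, exact sign-flip test, adjusted p = 0.0349) and passed camera (adjusted p = 7.38e-05, and adjusted p = 0.626 with an estimated correlation). Of 11 mural and meningeal markers none was called as deposited or over the list alone and 1 was lower median-scaled (camera down, adjusted p = 0.00711, and adjusted p = 0.852 with an estimated correlation). SPP1 and HSPB1 rose by 0.84 and 0.49 and C3 fell by 0.44 among 15 reactive gliosis genes, where 3 were higher and 1 lower, 2 and 1 adjusted over the list alone and 1 and 1 median-scaled (camera adjusted p = 0.208). IFIT1 and IFI6 rose by 0.49 and 0.30 and MX2 fell by 0.49 among 12 interferon-stimulated genes, where 3 were higher and 2 lower over all genes and adjusted over the list alone, and 1 was higher and 4 lower median-scaled (camera adjusted p = 0.165).

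ALDH1A1, a retinaldehyde dehydrogenase, fell by 0.28 on the log2 scale and was the single call among 12 genes of ethanol and aldehyde metabolism, with 0 adjusted over the list alone and 5 lower median-scaled (camera adjusted p = 0.225). SOD1, NFE2L2, TXN and PRDX2 rose by 0.25, 0.49, 0.25 and 0.19, the 4 calls among 18 oxidative stress genes, 4 adjusted over the list alone, with 1 higher and 2 lower median-scaled (camera adjusted p = 0.922). SQLE and IDI1 rose by 0.36 and 0.35, in a list of 18 cholesterol synthesis genes with 4 higher, 0 adjusted over the list alone, with 0 higher and 4 lower median-scaled (camera adjusted p = 0.676). HDAC2, HDAC9, TET2 and KDM5C rose by 0.46, 0.47, 0.35 and 0.38 among 21 chromatin modifiers, of which 5 rose, 4 adjusted over the list alone, with 2 higher and 2 lower median-scaled (camera adjusted p = 0.983). The changes of SQLE (-0.13) and HDAC9 (-0.07) turned sign with the composition covariates. NDUFB4 and ATP5A1 rose by 0.29 and 0.35 among 56 nuclear subunits of oxidative phosphorylation, of which 21 rose, 23 adjusted over the list alone, with 0 higher and 1 lower median-scaled (camera adjusted p = 0.32). Of 78 cytosolic ribosomal protein genes RPL7L1 rose by 0.37, and 4 were lower, among them RPLP2, RPL13 and RPL37 at -0.18, -0.16 and -0.20, with 0 adjusted over the list alone and 30 lower median-scaled (camera down, adjusted p = 1.88e-12, and adjusted p = 0.626 with an estimated correlation). With the composition covariates camera called this list the other way (adjusted p = 1.07e-11), and RPL7L1 (-0.12) and RPLP2 (0.02) turned sign. Of the 13 mitochondrially encoded genes ND6 and COX2 fell by 0.25 and 0.23, with 0 adjusted over the list alone and 4 lower median-scaled (camera down, adjusted p = 8.88e-08, and adjusted p = 0.458 with an estimated correlation). This list too was called the other way with the composition covariates (adjusted p = 3.02e-07), where ND6 had 0.07 and COX2 0.17. In all, camera with its preset correlation called 11 of 34 lists, 3 up and 8 down, and 0 with an estimated correlation, and the per-animal sign-flip test called 7. Fry, which sets a list against no change and not against other genes, called 13, 12 up and 1 down, of which 4 were also called by camera. After median scaling camera called 16, 7 up and 9 down, with oligodendrocyte markers (adjusted p = 0.0475) and the glucocorticoid list (adjusted p = 0.0308) added up, ethanol metabolism (adjusted p = 0.0199) added down and the mural list lost (adjusted p = 0.114). No estimated correlation was run for these either. The unadjusted sign-flip p was below 0.05 for 16 lists.

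Drinkers on their own showed the same leading genes, which had been picked over 16 pairs that include these animals. In the 10 drinkers DUSP4 rose by a log2 value of 2.16 ± 0.15 (SE, adjusted p = 3.73e-08), DUSP6 by 1.95 ± 0.23, CLK1 by 1.70 ± 0.14, SPRY4 by 1.51 ± 0.15, PER2 by 1.14 ± 0.12 and BHLHE40 by 1.29 ± 0.16, each in 10 of 10 animals. The myelin genes UGT8 and ERMN rose by 1.46 and 1.31, each in 9 of 10 drinkers. TYROBP fell by 0.67 in 9 of 10, and S100A8 fell by 2.39. NFE2L2, a regulator of antioxidant genes, rose by 0.72. By limma-trend 5500 genes changed in drinkers, 5005 higher and 495 lower, and 4608 changed after median scaling, 1908 higher and 2700 lower. Of the lists, camera called heat shock proteins up and 7 down, the microglial, endothelial, mural, blood, innate immune, ribosomal and mitochondrial lists, and 0 of them with an estimated correlation (smallest adjusted p = 0.665 with an estimated correlation). The number of lists that passed the exact sign-flip test was 0 (8 at an unadjusted p below 0.05, smallest adjusted p = 0.0664). The count was 3508 without drinker X10201 and 3607 without drinker X10227, 1601 in the pairs whose libraries carry a single RNA code, and 80 with the composition covariates.

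The controls addressed whether such changes also occur between biopsies of animals that the header does not mark as drinkers. The leading genes were the same, though picked over 16 pairs that include these 6 animals. In the 6 controls DUSP4 rose by a log2 value of 2.23 ± 0.19 (SE, adjusted p = 2.13e-06), DUSP6 by 1.70 ± 0.29, SPRY4 by 1.64 ± 0.20, BHLHE40 by 1.32 ± 0.20, PER2 by 1.27 ± 0.15, CLK1 by 1.11 ± 0.18, SPRY2 by 0.94 ± 0.19 and CRH by 0.72, each in 6 of 6 animals. LFNG fell by 0.77 in 6 of 6. Picked after their values were seen, the kinase gene SIK1, the receptor gene GPR3 and the pseudokinase gene TRIB2 rose by 1.52, 1.26 and 0.85 in controls and by 1.42, 1.26 and 0.96 in drinkers. TYROBP had a change of -0.52 ± 0.20 in controls (adjusted p = 0.292) and HSPA8 of 0.56 (adjusted p = 0.192), each with its sign in 6 of 6 animals. By limma-trend 46 genes changed in controls, 38 higher and 8 lower, and 95 after median scaling, 64 higher and 31 lower. Of the 46, 43 also changed in drinkers in the same direction, 37 higher and 6 lower, where independent lists of these sizes would share 12.7. Both sets of calls share a spread estimate per gene, so they are not fully independent and 12.7 may be too low. All 43 had 1 sign in drinkers and controls of each cohort, which is not independent evidence, since calls in the same animals picked them. Over the 16 pairs with the composition covariates 18 of the 43 stayed called, among them DUSP4, PER2, SPRY4, BHLHE40, GPR3, SIK1, CLK1, DUSP6 and CRH. Camera called 15 lists in controls, 6 up and 9 down, and 0 with an estimated correlation (smallest adjusted p = 0.322 with an estimated correlation). The exact sign-flip test called 0, with 4 at an unadjusted p below 0.05 and 0.03125 as the smallest p that 6 animals allow. The count of 46 fell to 6, 10, 13, 12 and 16 without animal X10197, X10198, X10204, X10232 or X10233, to 9 when the controls were fitted alone, to 19 without the animal block, to 13 in pairs with a single RNA code and to 11 with the composition covariates.

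**Figure D4:**
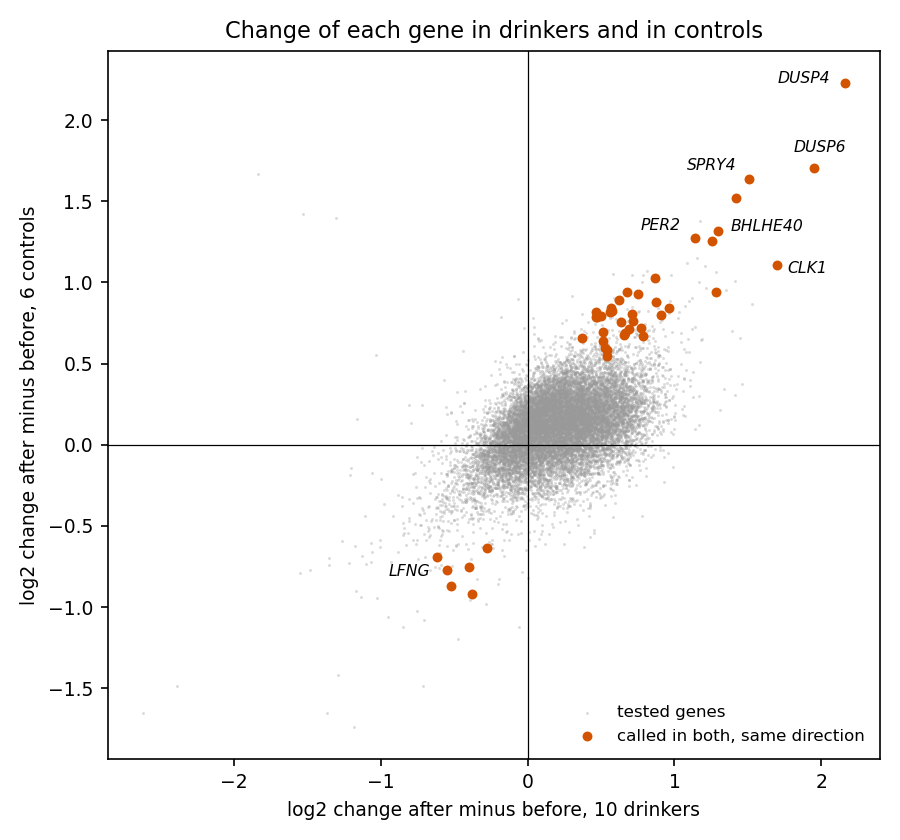
Log2 change from before to after of each of the 15324 tested genes (grey) in 10 drinkers (horizontal axis) and 6 controls (vertical axis), with the 43 genes that changed in both in the same direction in orange. DUSP4 lies at 2.16 in drinkers and 2.23 in controls.

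Across genes, which are not independent replicates, the changes of drinkers and controls had a Pearson r of 0.51 and a Spearman rho of 0.45. That relation was not seen within both cohorts: r was 0.82 in cohort 9 and -0.13 in cohort 13, and 0.82 and -0.16 after median scaling. In cohort 13, the before libraries of drinkers X10226 and X10227 share their RNA code with the after library of control X10232. The partner library of each carries another code. An effect of the code could thus push drinkers and controls apart in this cohort. No r was taken without these animals, so -0.13 does not settle whether the relation fails there. DUSP4, PER2 and the other genes called in both kept their sign in the 3 controls of cohort 13. The calls that picked these genes include those 3 controls, so this was favoured in advance. Across genes r was -0.17 between these controls and the drinkers of cohort 9, and 0.63 between the drinkers of cohort 13 and the controls of cohort 9.

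The difference between the change in drinkers and the change in controls asked which changes go with drinking. The microglia gene GPR34 changed by -0.06 ± 0.19 (SE, n = 10) in drinkers and -1.13 ± 0.24 (n = 6) in controls, a difference of 1.07 (adjusted p = 0.634). The astrocyte gene ETNPPL differed by 0.64, PON2 by 0.72, KAT2B by 0.75, NUDCD2 by 0.73 and RIDA by 0.64, and DBP, FOXM1, HCST, SLC25A41 and DTX2 differed by -0.58, -0.39, -0.53, -0.51 and -0.44, each at an adjusted p of 0.634. KAT2B was higher after in 10 of 10 drinkers and 2 of 6 controls, and PON2 in 7 of 10 drinkers and 0 of 6 controls. No gene passed the test: limma-trend called 0 of 15324 genes with 1036 at an unadjusted p below 0.05, limma-voom on recovered reads 0 with 1848, and the median-scaled fit 0 with 1651. Among the lists, camera placed oligodendrocyte markers (median difference 0.79) and ethanol and aldehyde metabolism (0.24) higher and blood markers (-0.79) lower in drinkers, each at an adjusted p of 0.0138, and none of them with an estimated correlation (adjusted p = 0.986 with an estimated correlation) or in a permutation test over animals (smallest adjusted p = 0.659, 1 list at an unadjusted p below 0.05). With 200 genes changed together, simulated differences of 1 on the log2 scale were called for 72% of them in this contrast. Differences of 0.5 were called for 0.5%, so differences of the smaller size were rarely detectable with these animals. Where fewer genes differ the adjustment is stricter, so 72% may be too high for a few genes, and GPR34 at 1.07 did not pass.

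The cohorts were compared because they differ in depth and RNA codes, and because a change in one of them is a difference only if the interaction passes. In the 8 animals of cohort 9 the cytokine genes TNF, CCL3 and CXCL8, the cholesterol hydroxylase gene CH25H and the serine dehydratase gene SDS fell, with log2 changes of -1.87, -2.56, -2.05, -1.67 and -1.13, where cohort 13 had -0.11, -0.11, 0.05, -0.03 and -0.29, none of them called. FOS rose by 2.37 in cohort 13 (adjusted p = 0.00248) and had -0.06 in cohort 9, and the difference did not pass (adjusted p = 0.169). NPY, DGKH, OLAH, ZNF483 and KCNH7 rose in cohort 9 by 1.01, 0.95, 0.81, 1.55 and 1.18, against -0.22, -0.06, -0.19, 0.09 and -0.05 in cohort 13. DUSP4 rose by 2.27 and 2.10, PER2 by 1.27 and 1.11 and SPRY4 by 1.60 and 1.52 in cohorts 9 and 13. Of the differences between cohorts, limma-trend called 2, TNF at 1.77 (adjusted p = 0.0189) and LOC102118223, a protein-coding gene without a symbol, at 2.91 (adjusted p = 0.0096), with 1148 genes at an unadjusted p below 0.05. Both were near the detection floor after, at 0.30 ± 0.19 and 0.45 ± 0.36 TPM in drinkers. Within cohort 9 5395 genes changed, 4676 higher and 719 lower (4295 median-scaled, 1797 higher and 2498 lower), and within cohort 13 164, 156 higher and 8 lower (167 median-scaled, 114 higher and 53 lower). The count in cohort 9 was 3033, 2862 and 3223 without animal X10197, X10201 or X10203, and that in cohort 13 was 93, 62, 60 and 105 without animal X10233, X10227, X10229 or X10236, 26 fitted alone, 31 with a single RNA code per pair and 91 without the animal block. The 2 differences became 5 after median scaling, 1 other gene in pairs with a single RNA code and 0 by limma-voom with 1729 at an unadjusted p below 0.05.

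Relative to all genes, immediate early genes had a median log2 change of 0.88 in cohort 13 and -0.07 in cohort 9. Oligodendrocyte markers had -0.16 in cohort 13 and 0.64 in cohort 9. Camera on the interaction called 7 of 34 lists. Immediate early (adjusted p = 1.05e-11), blood (adjusted p = 2.48e-10), innate immune (adjusted p = 2.48e-10), microglial (adjusted p = 0.00353) and ribosomal (adjusted p = 8.71e-13) lists were higher and oligodendrocyte (adjusted p = 5.25e-07) and potassium channel (adjusted p = 0.0436) lists lower in cohort 13. With an estimated correlation 0 were called (smallest adjusted p = 0.325 with an estimated correlation), fry called 0, and a permutation test over animals called 0 (smallest adjusted p = 0.145, 5 lists at an unadjusted p below 0.05).

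The authors' deposited fold changes and FDR values were described without a test. In their table NAB2, a repressor of EGR1, had a log2 change of 0.69 in controls and 0.33 in drinkers, FAM212B 0.78 and 0.40, C1QTNF2 0.71 and 0.38, ITPRIPL1 0.76 and 0.47 and PDCD7 0.59 and 0.55, all with an FDR below 0.05 in both. On the lower side GPR34 had -1.38 in controls and -0.28 in drinkers, RPE65 -1.39 and -0.49, MEX3B -0.88 and -0.43, RAPGEF4 -0.74 and -0.37 and ETNPPL -0.70 and -0.16. Their table holds 5599 genes with an FDR below 0.05 in drinkers and 336 in controls, with 243 in both, all 243 of the same sign. Their sheets list 567 genes as higher and 675 as lower in drinkers and 39 and 38 in controls. Of the 1341 genes that met the apparent criteria in drinkers and the 176 in controls, the 99 that met both are absent from all these sheets. Of the 38 genes on the sheet of falls in controls, the difference between drinkers and controls passed the test here for 11 when adjusted over that sheet alone (smallest adjusted p = 0.0269), a sheet chosen on these same animals and so not independent evidence, and for 0 genes of the other sheets. Across genes, which are not independent replicates, the authors' changes had a Pearson r of 0.97 in drinkers and 0.96 in controls with those of the fit here over 15304 genes, and 47.8% of their drinker calls were higher, against 91% here as deposited and 41.4% after median scaling.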

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

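The tests of the mitochondrial share and of ethanol alone were written after the results were seen. Most called genes were higher after as deposited, and the mean over animals of the median log2 change was 0.173 ± 0.056 (SE, n = 16). A lower mitochondrial share might raise all other genes. Without the mitochondrially encoded genes that mean was 0.058 ± 0.026, narrowly more than 2 SE above 0. It was taken over the 16576 genes that then passed the filter, against 15324 as deposited. The share may thus account for much of the shift, and so narrow a margin over unlike sets of genes does not settle whether for all of it. Without the mitochondrially encoded genes 2785 genes were called higher and 1528 lower. With the mitochondrial percent as a covariate 600 genes were called and the median change over genes was 0.028 in place of 0.174. Depth could also contribute. The log2 ratio of recovered reads went with the median change at r = 0.46 (permutation p = 0.0726) and rho 0.41 (permutation p = 0.113). It was r = 0.23 without the 2 farthest animals, 0.28 in cohort 9 and 0.56 in cohort 13. The recovered reads leave out 26 abundant genes, mitochondrially encoded ones among them. Their ratio therefore also rises when the mitochondrial share falls, so this is not a separate test of depth, and depth stays open.

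Drinkers and controls shared 43 called genes, DUSP4, PER2 and SPRY4 among them, against 12.7 by independent lists, so ethanol alone is not a likely source of these. The calls share a spread estimate per gene, so 12.7 may be too low. A batch difference could be shared as well. Among cohort 9 animals, all with a single RNA code, r across genes was 0.82 between drinkers and controls (-0.13 in cohort 13, 0.51 pooled). Genes are not independent replicates. A differing RNA code is thus not the source of that relation in cohort 9. In cohort 13 the code changes one way in drinkers X10226 and X10227 and the opposite way in control X10232. Whether this lowers r in that cohort was not tested and stays open. A before and after batch that the code does not mark was not tested and stays open. A shift in the neuron and glia content of the biopsy may carry part of the change, since 18 of the 43 stayed called with the composition covariates, a number that neither excludes nor establishes it. All 43 kept their sign in that fit, and 15 stayed called with these covariates and median scaling. Effects of time or of the earlier biopsy were not tested.

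Far more genes were called in drinkers (5500) than in controls (46). The larger number of drinkers may account for part of this: of 100 sets of 6 drinkers fitted alone, 70 gave more genes than the 9 of the controls fitted alone, with a median of 27.5 and a range of 2 to 6600. The root mean square change over genes less sampling error was 0.337 in drinkers and 0.166 in controls, with an SD between animals of 0.415 and 0.377, a difference that was not tested. Ethanol alone could also add to it, and with 0 genes whose change differed between drinkers and controls these cannot be told apart.

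Before and after were exchanged within animals at random. As many genes as the 5608 of the 16 pairs came in 1 of 100 regroupings, the real one (highest other 5038). For the 5500 of drinkers this was 1 of 100 (highest other 4) and for the 46 of controls 1 of 32 (highest other 0). For the 5395 of cohort 9 it was 1 of 100 (highest other 3382) and for the 164 of cohort 13 3 of 100 (highest other 2554). Counts as large as the real ones were thus rare under exchange. Exchanged labels still gave high counts at times in the 16 pairs and in each cohort, so chance is less likely there but not excluded. Of the random splits of the 16 pairs 2 called 100 or more genes, and the median over all splits other than the real one was 0. What set these 2 apart was not tested. For the 2 differences between cohorts 1 of 100, the real one, gave as many (highest other 1), which is too close to exclude chance. For the 0 differences between drinkers and controls 100 of 100 did (highest other 0), which a count of 0 fixes in advance, so this exchange decides nothing. For the 11 lists 48 of 100 gave as many (highest other 22), so chance could not be excluded there.

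A value far from the others was found in 10 of 86 groups, where chance alone gives about 1 in 20, or 4.3. The after biopsy of drinker X10230 had 26947 genes above 0 (others 20749 to 23730). The log2 change of CLK1 was 2.731 in drinker X10226 (others 1.123 to 1.96), that of SFRP2 4.163 in X10201 (others -0.153 to 1.945), that of PER2 1.861 in X10227 (others 0.716 to 1.315) and that of GFAP 2.273 in X10207 (others -0.168 to 1.07). Control X10204 had -2.914 for MNDA (others -0.711 to 0.166), -1.935 for ARPC1B (others -0.547 to 0.168), -1.32 for TYROBP (others -0.553 to -0.095) and -1.919 for SLC38A5 (others -0.648 to -0.024). HBB changed by 5.877 in control X10233 (others -0.551 to 1.749).

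Between cohorts, the change of LOC102118223 differed by 2.905 and that of TNF by 1.766. Between drinkers and controls, camera called the oligodendrocyte, blood and ethanol metabolism lists, each at an adjusted p of 0.0138 (adjusted p = 0.986 with an estimated correlation). Between cohorts it called the oligodendrocyte (5.25e-07), microglial (0.00353), blood (2.48e-10), immediate early (1.05e-11), innate immune (2.48e-10), potassium channel (0.0436) and ribosomal lists (8.71e-13), with a smallest adjusted p of 0.325 with an estimated correlation.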

How the results depend on the processing

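Most counts moved with composition, scaling and single animals, and except where stated the cause was not tested. The 5608 genes changed over the 16 pairs became 108 with the composition covariates, 115 with these and median scaling, 600 with the mitochondrial percent as a covariate, 3569 by limma-voom and 1271 at an absolute log2 of at least 0.5, which by construction keeps a subset. Leaving out 1 animal gave 4063 to 6704. It stayed between 3834 (median scaling) and 6353 (array weights) under other filters, pseudocounts, scalings, robust estimation, a single RNA code and no animal block (4303). The 5500 of drinkers became 1601 with a single RNA code, 80 with the composition covariates and 178 with these and median scaling, and 3508 (without X10201) to 6900 (without X10230) with 1 animal left out, 3607 without X10227. The 46 of controls became 19 without the animal block, 95 with median and 92 with trimmed-mean scaling, 13 with a single RNA code, 11 with the composition covariates, 8 with these and median scaling, 100 by limma-voom, 91 without mitochondrial genes and 9 fitted alone. Leaving out 1 control gave 6 (without X10197) to 33 (without X10234), with 10 without X10198, 13 without X10204, 12 without X10232 and 16 without X10233. The difference between drinkers and controls stayed at 0 throughout, with 196 to 2593 genes at an unadjusted p below 0.05 over the refits.

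The 5395 of cohort 9 became 7776 fitted alone and 2862 (without X10201) to 5571 with 1 animal left out, 3033 without X10197 and 3223 without X10203. The 164 of cohort 13 became 26 fitted alone, 31 with a single RNA code, 91 without the animal block and 60 (without X10229) to 214 with 1 animal left out, 62 without X10227, 93 without X10233 and 105 without X10236. The 2 cohort differences became 5 with median scaling, 1 with a single RNA code and 0 by limma-voom. Leaving out 1 animal gave 1 (without X10197, X10203, X10207, X10232, X10234, X10227, X10229 or X10230) to 7 (without X10204), with 4 without X10198 or X10200 and 5 without X10226. The 11 lists became 0 with the estimated correlation, 7 by per-animal sign flips, 16 with median scaling, 13 by fry, 4 of them shared, and 10 without X10230. Leaving out the animal block moved no other count by over 1.5 times, and of the named genes compared 84 stayed the same and 8 were weaker, with none reversed. With the composition covariates 19 stayed the same, 58 were weaker and 15 reversed in sign, whether or not called in that fit. Weaker here means a lost call, which is not always a smaller change. Depth limits the genes near the detection floor, TNF among them.

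With the composition covariates 4 lists turned direction, reactive gliosis (adjusted p = 0.0103), presynaptic (0.0118), ribosomal (1.07e-11) and mitochondrially encoded genes (3.02e-07), the innate immune list lost its call (0.68), and postsynaptic scaffold genes (8.05e-07) and nuclear oxidative phosphorylation genes (1.74e-06) gained one. Turned in sign were the log2 changes of GRIA2 (-0.063), GRIA3 (-0.136), GRIN2B (-0.11), GRM8 (-0.097), GRM4 (-0.026), GABRA4 (-0.166), DLG3 (-0.13), CACNA2D3 (-0.065), SCN3A (-0.02), SQLE (-0.13), HDAC9 (-0.065), RPL7L1 (-0.124), RPLP2 (0.018), ND6 (0.072) and COX2 (0.168). Several of these values lie near 0. Not run were the fit of all 38 samples, of which 6 were not analysed here, and surrogate variables and DESeq2 size factors, in whose place median scaling stands.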

Other observations

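FOS and the activity-regulated transcription factor NPAS4 were highest in 3 libraries, the before biopsy of control X10204 (219.5 and 30.7 TPM) and the after biopsies of control X10198 (169.4 and 41.5 TPM) and drinker X10230 (131.9 and 19.2 TPM).

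The following idea and its test were chosen after the results were seen. PER2 and BHLHE40 rose in 16 of 16 animals, which might reflect after biopsies taken at another phase of the daily clock. Of the clock output genes PER3, NR1D1, NR1D2, DBP, TEF, CIART and BHLHE41, 1 of 7 was called higher, NR1D2 at a log2 value of 0.66, and CIART fell by 0.53. After median scaling 5 of the 7 were called, NR1D2 higher at 0.43 and DBP, TEF, CIART and BHLHE41 lower at -0.38, -0.42, -0.74 and -0.18. NR1D2 had 0.007 and was not called with the composition covariates, where of the 7 only CIART was called, at -0.80. Clock genes peak at different times of day, so a shift of phase forbids none of these directions, and the count of higher calls excludes nothing. A shift of phase stays open, since times of day are not given in the sources used here.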
